A study of Mus musculus with 2 samples.

How the data were processed

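H3K4me2 ChIP-seq of hindbrain tissue from mouse embryos at day 14.5 was deposited by an ENCODE laboratory for 2 libraries, each from its own pool of 24 or 34 embryos, per the labels. The libraries were biological replicates 1 and 2 of a single group. The labels give separate pools, so the spread between the replicates holds biological and technical variation. Each replicate had its own list of peaks, and further lists were made from the reads of both replicates pooled and, as replicated peaks, from the pooled list together with the lists of both replicates, per the deposited descriptions of the files. Each replicate was set against its own control alignment and the pooled list against both controls, per the same descriptions. Reads were filtered after alignment and the assembly was mm10, per the deposited descriptions. The aligner, the peak caller, their versions and the rule for a replicated peak are not given in the sources used here.

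Peaks came in the narrowPeak layout as deposited. The signal of a peak is the enrichment that the authors' peak caller gave it, and its scaling is not given in the sources used here. The −log10 p and −log10 q of a peak were also given by the authors' caller in the deposited lists, and the smallest −log10 p was 2.07, 2.00 and 2.01 in the lists of replicate 1, replicate 2 and the pooled reads, so weak peaks are included. Of the peaks, 77.3%, 77.2% and 83.2% in those lists had a −log10 p of 5 or more. All 35769 replicated peaks were found as entries of the pooled list, with the values of that list. Signal values were used only to describe and rank peaks within a list and to compare both replicates peak by peak. The depth of the libraries is unknown, so the precision that depth gives could not be worked out.

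Everything else was computed from the deposited lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on unplaced or unlocalised scaffolds were left out (18, 16, 16 and 15 in the lists of replicate 1, replicate 2, the pooled reads and the replicated peaks), which kept 19 autosomes, X and Y. The reference was the mm10 sequence with the basic gene annotation of GENCODE release M21. Coordinates are 1-based on mm10. The unit of analysis was the protein-coding gene with its 41438 TSS of protein-coding transcripts. A gene was marked when a peak reached within 500 bp of any of its TSS. Breadth was the number of bases in peaks within 5 kb on either side of the TSS with the most such bases, so 10 kb is its ceiling. Domains were replicated peaks joined over gaps of up to 1 kb.

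Overlap between the replicates counted peaks sharing at least 1 bp and was set against 100 random placements of the list within its chromosomes, outside assembly gaps of 100 bp or more. The same placements served the shares of peaks near any annotated TSS (1 kb), then in exons, introns and between genes, in that order. Shares of marked genes per list were compared with all other protein-coding genes by two-sided Fisher's exact test, and breadth with 10000 random lists of equal size by two-sided permutation, each with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Breadth was tested for lists with at least 5 marked genes. Intervals of shares are exact Clopper-Pearson intervals at 95% and describe a list's size only. For Hox genes the covered share ran from 2 kb upstream of the gene to its end, with a permutation test of 100000 resamples. For sequence words, windows of 200 bp at the summits of peaks more than 2 kb from any TSS were compared with windows of 200 bp placed 2 kb to either side outside all peaks, by Fisher's exact test over 17 words.

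The gene lists, the words, the tests and the alternatives were chosen before the data were examined, apart from those named as later choices. There were 22 lists with 1829 matched genes: hindbrain and cerebellar regulators, forebrain regulators, anterior Hox genes, posterior Hox genes, neural progenitors, pan-neuronal genes, transmitter and hindbrain neuron classes, astrocytes and oligodendrocytes, patterning signals, cell cycle, endothelium and pericytes, microglia and other immune cells, erythroid cells, meninges and mesenchyme, choroid plexus and ependyma, hepatocytes, cardiac and skeletal muscle, epithelium, germline, pluripotency, housekeeping, and olfactory and vomeronasal receptors. The erythroid gene Ahsp was not matched in the annotation and was left out. Genes named in the text are, per list, the 3 members with the most bases in peaks within 5 kb and up to 2 with the fewest, ties in alphabetical order. The rule also names the marked members of non-neural lists up to 4, all Hox genes, the 10 longest domains that hold a protein-coding TSS, the 5 peaks with the highest signal and, each way, the 5 strongest promoters found in 1 replicate only. Other names were chosen after their values were seen.

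Alternatives were a minimum −log10 p of 5, the pooled list, each replicate's own list, a reciprocal overlap of 50%, windows of 2 kb, the length of the merged domain, 1 kb around the TSS of Hox genes, genes matched on promoter CpG observed over expected in 10 bins, and flanks matched on GC content in bins of 5 points. The use of only the most upstream TSS was added after seeing the data. CpG ratios were taken over 500 bp on either side of the TSS.

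The tests were first tried on simulated data. With marks drawn at random over 21851 genes, 0 of 440 tests of a list were called, and 100 of 100 lists planted at a low share were found. For breadth, 0 of 219 tests were called without an effect and 48 of 50 planted lists were found. For 31 genes, the number in the Hox test, 16 of 400 null data sets gave p under 0.05 and 100 of 100 planted differences did. These values were drawn independently for each gene, and the planted groups did not overlap. Neighbouring Hox genes share peaks, so those rates do not carry over to the Hox test. In the word test, the planted word was found, and 1 of 3 other words was also called in that simulated set. A larger simulation without effects, added after that call was seen, gave an unadjusted p under 0.05 for 40 of 800 words (5%) and a call after adjustment for 12 of 800 (1.5%). All simulated windows were drawn with equal base frequencies, and simulated marks did not depend on promoter CpG content. These trials therefore do not show how often base composition alone gives a call in the real data.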

Results

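Dimethylation of lysine 4 on histone H3 (H3K4me2), a chromatin mark found at promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse hindbrain at embryonic day 14.5. The design held 1 group with 2 biological replicates. Replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34 embryos, each of mixed sex. The authors listed 46234 peaks in replicate 1 (median width 710 bp, 55.7 Mb in all), 48451 in replicate 2 (643 bp, 53.8 Mb) and 48017 on the pooled reads of both (749 bp, 62.1 Mb). Their replicated list, made from the pooled list, held 35769 peaks with a median width of 1141 bp that covered 58.5 Mb. Read counts were not given in the sources used here, so the depth of each library is unknown, and the signal of a peak is the authors' own value. With 1 group there was no contrast of conditions. The comparisons were between the replicates, between gene groups within the replicated peaks, and between those peaks and random positions of the mm10 genome.

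The first comparison asked how far the replicates placed the mark at the same sites. Of 46216 peaks of replicate 1 on the assembled chromosomes, 80.4% touched a peak of replicate 2, and 81.1% of 48435 replicate 2 peaks touched a peak of replicate 1. Random placement of the list within its chromosomes gave means of 4.00% and 3.91%, with maxima of 4.27% and 4.10% (one-sided permutation p = 0.009901 each, the smallest that 100 placements can give). The bases shared by both replicates made up 78.0% of the bases in either. Across 37178 touching pairs, the rank correlation of the authors' signal was 0.832, and the log2 ratio of replicate 1 to replicate 2 had a median of -0.04 and an SD of 0.69. Peaks are not independent replicates, so no p-value was attached to that correlation. Of the protein-coding genes, 14270 had a peak within 500 bp of a transcription start site (TSS) in both replicates, 103 in replicate 1 only and 136 in replicate 2 only.

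Promoters of E130218I03Rik, Lor (loricrin, of the cornified skin layer), Angptl6, Hcrt (the hypothalamic neuropeptide orexin) and Mroh6 had the strongest peaks among those reached in replicate 1 only, with −log10 p of 195.9, 113.6, 100.9, 99.3 and 86.0. In replicate 2 only, the strongest stood at Tmem79, 4930451I11Rik, Abca15, Gm5294 and Znrf4, with −log10 p of 92.0, 71.7, 55.4, 23.7 and 18.5. All 5 of the first group and Tmem79, 4930451I11Rik and Abca15 of the second were marked in the replicated list, as were 30 of the 103 and 45 of the 136 genes. These counts therefore depend on whether a peak reaches to within 500 bp of a TSS in each list. Most such peaks were weak. Their median −log10 p was 4.81 over the 103 genes of replicate 1 and 5.02 over the 136 genes of replicate 2, against 137.7 over 500 genes drawn from those with a peak in both. Among the members of the gene lists, 9 had a peak within 500 bp of a TSS in replicate 1 only (Aqp1, Cdh5, Col3a1, Phox2b, Prdm14, Tdgf1, Tek, Tie1 and Trp63) and 5 in replicate 2 only (Actc1, Cldn7, Dcn, Kcne2 and Tbr1). Within 5 kb, replicate 2 still had 2.18 kb of peaks at Phox2b, 1.001 kb at Prdm14, 0.812 kb at Col3a1, 0.645 kb at Cdh5, 0.589 kb at Aqp1 and 0.351 kb at Tdgf1. Replicate 1 likewise had 0.623 kb at Cldn7, 0.405 kb at Dcn and 0.252 kb at Kcne2. These 14 names are given in full and were not chosen by the rule for named genes. There was 1 library on each side, so no test was made.

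Promoters held close to 50% of the replicated peaks. Within 1 kb of a TSS lay 17903 of 35754 peaks (50.1%), against a mean of 7.77% for random placements, a 6.45-fold excess. Exons beyond that distance held 6.76% of peaks (10.16% by random placement), introns 22.9% (33.9%) and the space between genes 20.3% (48.2%). Each of these 4 shares lay outside all 100 placements (permutation p = 0.009901, one-sided in the direction seen, the smallest they can give). The promoter share depended on the list of peaks. It was 39.95% on the pooled list, 42.9% without replicate 1 and 42.8% without replicate 2, against random means of 7.09%, 6.76% and 6.93%. With a −log10 p of at least 5 it was 50.8%, and within 2 kb of a TSS 54.4%. Peaks near a TSS had a median width of 2084 bp and a median signal of 28.1, and the 17851 farther peaks had 693 bp and 5.002. The 5 peaks with the highest signal in the replicated list included those at the TSS of Pik3ip1 (a negative regulator of PI3 kinase; 11:3330031-3333094, signal 70.6), Nr3c2 (the mineralocorticoid receptor; 68.7), Vgf (a secreted neuropeptide precursor; 68.4) and Adgrg6 (an adhesion G protein-coupled receptor needed for peripheral myelin; 68.2). The remaining peak, at 10:60685868-60687948 with a signal of 68.2, lay 8542 bp from the nearest TSS, that of Cdh23.

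Every gene of the hindbrain and cerebellar regulator list carried a replicated H3K4me2 peak at a promoter. In the replicates' own lists, 24 were marked in replicate 1 and 23 in replicate 2, where Phox2b was not marked. All 24 members, among them En1 (an engrailed homeobox gene of the midbrain-hindbrain boundary) and Atoh1 (the proneural gene of the rhombic lip), had a replicated peak within 500 bp of a TSS (exact 95% interval 85.8% to 100%), against 65.7% of the other 21827 protein-coding genes. The anterior Hox list was marked at 15 of 15 genes. Neural progenitor genes, pan-neuronal genes, patterning signals and cell cycle genes were each marked at 20 of 20 members, and housekeeping genes at 26 of 26. Of the transmitter and hindbrain neuron class genes, 17 of 19 were marked, and the 2 without a peak were Dbh and Th, enzymes of noradrenaline and dopamine synthesis. In all, 14353 of 21851 protein-coding genes were marked (65.7%), and the replicates' own lists gave 65.85% ± 0.107 (mean ± SD, n = 2).

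These 8 lists exceeded the other genes by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 22 lists. Adjusted p was 0.000221 for hindbrain regulators, 0.00405 for anterior Hox genes, 0.000926 for each of the 4 lists of 20 genes, 0.0458 for transmitter genes and 0.000211 for housekeeping genes. Genes are not replicates, so the tests describe these lists in this set of peaks. With the background matched on promoter CpG content, none of the 8 lists was called. Lists marked at every member already had the highest possible share, so the matched test could not have called them. It therefore does not show that CpG content accounts for their excess. Matched genes were themselves mostly marked (97.4% for hindbrain regulators, 84.9% for anterior Hox genes, 97.6% for housekeeping genes and 82.0% for transmitter genes), and a window of 2 kb ended the call of the transmitter genes (89.5% against 67.1% of other genes, adjusted p = 0.0703 by Fisher's exact test) with their share unchanged.

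The mark was less frequent at 6 lists than at the other genes. Hepatocyte genes carried a replicated promoter peak at 1 of 16 members, Foxa3 (a forkhead factor of endoderm), while the plasma protein genes Afp and Ahsg had no replicated peak within 5 kb. Germline genes were marked at 2 of 15 members, Dazl and Zpbp, and cardiac and skeletal muscle genes at 3 of 17, namely Gata4, Myod1 and Ryr1. Of the microglial and other immune genes, 3 of 16 were marked (Irf8, P2ry12 and Runx1), and Aif1 and C1qb, markers of macrophages and microglia, had no peak within 5 kb. Erythroid genes were marked at 5 of 15 members, Epor, Gypa, Klf1, Nfe2 and Tal1, and not at Alas2 or Gata1. Only 4 of 1463 olfactory and vomeronasal receptor genes were marked (0.273%, exact 95% interval 0.0745% to 0.699%), against 70.4% of the other 20388 genes. They were Olfr1033, Olfr658, Olfr94 and Vmn1r4.

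Each of those 6 lists fell below the other genes by the same two-sided exact test, with adjusted p of 1.27e-05 for hepatocyte, 0.000221 for germline, 0.000245 for muscle, 0.000508 for immune and 0.0211 for erythroid genes. The p-value of the receptor genes was too small for the program to represent. Against genes matched on promoter CpG content, the germline list (68.0% of matched genes marked) and the receptors (6.97%) stayed below, both with adjusted permutation p = 0.00147. Hepatocyte genes (29.0%), immune genes (29.8%) and muscle genes (32.1%) then missed the threshold, the direction turned for erythroid genes (18.97%), and a 2 kb window raised the marked share of muscle genes to 41.2% (adjusted p = 0.0556, Fisher's exact test). That window also raised hepatocyte genes to 25% and germline genes to 33.3%, which stayed below the other genes (adjusted p = 0.00168 and 0.0186, Fisher's exact test).

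The other 8 lists did not differ from the remaining genes in marked promoters. Forebrain regulators, which pattern or specify the telencephalon, hypothalamus and cortex, were marked at 18 of 21 members (85.7%, adjusted p = 0.0949 by Fisher's exact test), and Dlx1, Fezf2 and Tbr1 lacked a peak. Genes of meninges and mesenchyme were marked at 14 of 16 (0.0966), without Col3a1 and Lum. Posterior Hox genes were marked at 7 of 16 (0.142). Endothelial and pericyte genes were marked at 12 of 16 (0.660), without Cdh5, Pecam1, Tek and Tie1. Astrocyte and oligodendrocyte genes were marked at 14 of 20 (0.855), and the myelin genes Mag and Mobp had no peak within 5 kb. Choroid plexus and ependymal genes were marked at 8 of 12 (adjusted p = 1 by the exact test), without Aqp1, Folr1, Kcne2 and Ttr. Epithelial genes were marked at 7 of 12 (0.648), without Cldn7, Krt14, Krt5, Krt8 and Trp63. Pluripotency genes were marked at 5 of 10 (0.399), and Dppa4, Dppa5a, Nanog, Pou5f1 and Zfp42 lacked a peak. Unmarked members were named in full for lists with 5 or fewer, after the values were seen.

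Some of these 8 results depended on the peaks used. On the pooled list the forebrain regulators (90.5%, adjusted p = 0.0265), endothelial genes (93.8%, 0.0251) and meningeal genes (93.8%, 0.0251) passed as more often marked by Fisher's exact test. The forebrain list also passed without replicate 1 (0.0300) and with a 2 kb window (0.0341), and the endothelial list without replicate 2 (0.0259). Matched on CpG content, forebrain regulators lay below their matched genes (92.6% marked) with no call. Epithelial genes lay above the other genes in 4 of 7 alternatives, choroid plexus genes lay below them in 2 of 7 and astrocyte genes in 1 of 7, none with a call. Pluripotency genes were marked at 3 of 10 without replicate 1 (30%, adjusted p = 0.0519 by Fisher's exact test). Posterior Hox genes passed as less often marked once matched on promoter CpG content, where 94.6% of matched genes were marked (adjusted permutation p = 0.00147).

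**Figure D1:**
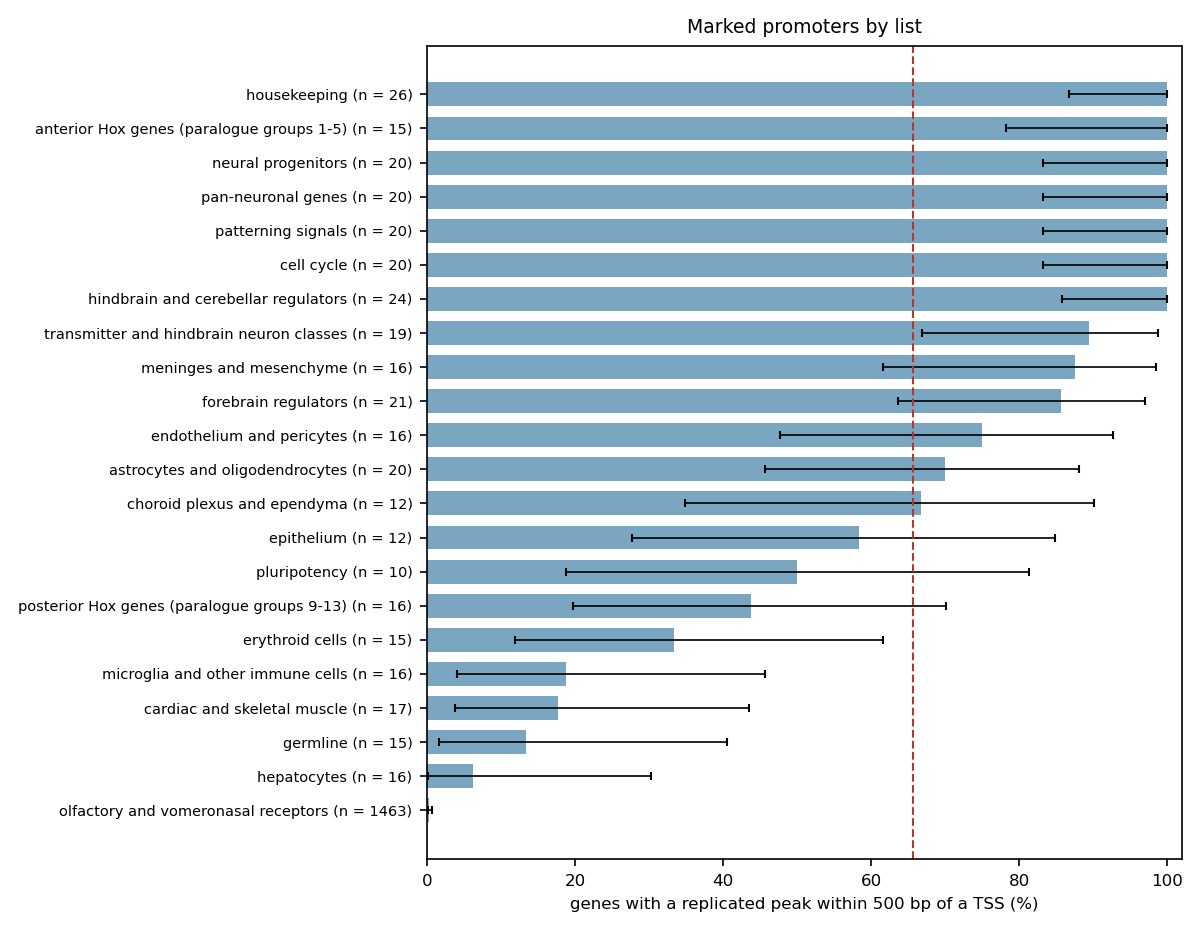
Share of protein-coding genes in each list (horizontal axis, percent) with a replicated H3K4me2 peak within 500 bp of a TSS, with exact 95% intervals as error bars and the share over all genes, 65.7%, as a dashed line. Lists of hindbrain regulators, neural progenitors and pan-neuronal genes stand at 100%, hepatocyte genes at 6.25% and olfactory and vomeronasal receptors at 0.273%.

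Marked hindbrain regulators carried broad H3K4me2. Replicated peaks covered a median of 9.14 kb of the 10 kb around the TSS of the 24 hindbrain and cerebellar regulators (quartiles 5.16 and 9.86 kb), 3.19 times the 2.86 kb of random marked genes. En1 (1:120602418-120607992), Lhx1 (11:84518284-84525535) and Lhx5 (5:120431699-120441223), homeobox genes of early neural patterning and Purkinje cell or interneuron development, were covered over all 10 kb. In the replicates' own lists, En1 had 9.86 ± 0.199 kb, Lhx1 10 ± 0 kb and Lhx5 9.95 ± 0.0792 kb (mean ± SD, n = 2). The least covered members were Ptf1a (2:19445663-19447501), the determinant of GABAergic cerebellar neurons, with 2.60 kb (2.37 ± 0.129 kb) and Atoh1 (6:64729125-64731245) with 3.349 kb (3.705 ± 0.362 kb).

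The mark was broad at 6 further lists. Anterior Hox genes had a median of 9.89 kb (3.45 times random lists). Neural progenitor genes had 6.89 kb (2.40 times), from 10 kb at Nfib and 9.72 kb at Nfia, nuclear factors of gliogenesis, and 9.02 kb at the Notch ligand gene Dll1, down to 2.95 kb at Prom1 and 1.63 kb at Neurog1. Pan-neuronal genes had 6.13 kb (2.14 times), led by the RNA-binding protein gene Elavl4 with 10 kb, the microtubule regulator gene Stmn1 with 8.93 kb and Celf4 with 8.71 kb. Dcx and Syp were the least covered, with 5.18 and 3.42 kb. Transmitter and neuron class genes had 4.28 kb (1.49 times), and 3 stood highest: Gata3 with 10 kb, the vesicular inhibitory amino acid transporter gene Slc32a1 with 10 kb and the neuronal glycine transporter gene Slc6a5 with 9.86 kb. Patterning signals had 4.28 kb (1.49 times), with 10 kb at the hedgehog receptor gene Ptch1, 9.94 kb at Wnt5a and 7.57 kb at Spry2, against 2.37 kb at Rspo1 and 1.22 kb at Fgf8. Housekeeping genes had 4.47 kb (1.56 times), from 8.55 kb at Tubb5, 6.36 kb at Polr2a and 5.94 kb at Eef2 to 2.00 kb at Psmb2 and 1.75 kb at Gusb.

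The mark was narrow at 4 lists. Marked forebrain regulators had a median of 2.08 kb, 0.723 times random lists. Bcl11b, Neurod6 and Satb2, genes of neuronal differentiation, were the broadest of them with 8.397, 5.95 and 5.47 kb. Posterior Hox genes had 0.989 kb over 7 marked genes (0.345 times), and the broadest were Hoxb9 with 1.78 kb, Hoxd13 with 1.45 kb and Hoxd9 with 1.15 kb. Epithelial genes had 1.70 kb over 7 genes (0.594 times), with 2.88 kb at Grhl2, 2.35 kb at Esrp1 and 1.71 kb at the E-cadherin gene Cdh1. Pluripotency genes had 1.25 kb over 5 genes (0.438 times), and their broadest were Esrrb with 5.23 kb, Prdm14 with 1.48 kb and Utf1 with 1.25 kb.

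Breadth was tested by permutation, two-sided, against 10000 random lists of marked genes, with Benjamini-Hochberg adjustment over the 17 lists with at least 5 marked genes. Hindbrain regulators, anterior Hox genes, progenitors and pan-neuronal genes had adjusted p = 0.00085, from an unadjusted p of 0.0002 that is the smallest these permutations can give. Adjusted permutation p was 0.0017 for housekeeping genes, 0.00583 for patterning signals and 0.0136 for transmitter genes. For the narrow lists it was 0.00136 (posterior Hox genes), 0.0123 (pluripotency), 0.0218 (forebrain regulators) and 0.0328 (epithelium). A 2 kb window ended the calls of patterning signals (2.82 kb against 2.58 kb in random lists, adjusted permutation p = 0.326) and epithelium (1.70 kb against 2.59 kb, 0.0612) and turned the direction of the transmitter genes (median 2.10 kb, 0.0935), which also missed the threshold without replicate 2 (3.02 kb against 2.73 kb, 0.511). The folds of the broadest lists depended on the ceiling of 10 kb. By the length of the merged domain, hindbrain regulators had 13.8 kb and anterior Hox genes 56.9 kb, each against 2.80 kb in random lists. Hoxa1 to Hoxa5 all lie in the same domain of 56.9 kb, which is counted again for each of them. Neighbouring Hox genes share peaks, and the random lists of marked genes do not take this into account. With the 2 kb window, whose ceiling is lower, both had 4.001 kb, progenitors 3.74 kb and pan-neuronal genes 3.42 kb, against 2.59 kb. With only the most upstream TSS of each gene, an alternative chosen after seeing the data, the forebrain list missed the threshold (2.45 kb against 2.84 kb, 0.399) and the pluripotency list had too few marked genes to test. It also had too few, 3, without replicate 1.

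Breadth at the remaining lists did not differ from that of random marked genes. Astrocyte and oligodendrocyte genes had a median of 3.97 kb (adjusted permutation p = 0.0531), led by Pdgfra with 6.98 kb, Slc1a2 with 6.77 kb and Olig2 with 5.85 kb. That list passed as broader on the pooled list (4.58 kb, 0.00977), without replicate 1 (3.78 kb, 0.0292), with CpG matching (0.0155) and by the length of the merged domain (4.05 kb, 0.0389). Cell cycle genes had 3.003 kb (0.812), with the D-type cyclin genes Ccnd2 and Ccnd1 at 8.01 and 6.79 kb, Mcm2 at 4.55 kb, and Tyms and Bub1 at 2.01 and 1.74 kb, and lay below random lists in 1 of 8 alternatives. Endothelial genes had 3.15 kb (0.684), with 4.13 kb at Pdgfrb, 3.87 kb at Sox18 and 3.52 kb at Esam. In 6 of 8 alternatives that list lay below random lists, with medians of 1.98 to 2.93 kb and no call. Erythroid genes had 1.67 kb over 5 genes (permutation, 0.0531), with 8.48 kb at Tal1, a hematopoietic factor that is also active in GABAergic neurons of the hindbrain, 2.07 kb at Epor and 1.67 kb at Klf1, and passed as narrower on the pooled list (0.0447). Meningeal genes had 2.94 kb (0.944), with Tfap2b at 8.998 kb, Prrx1 at 5.98 kb and Foxf2 at 5.65 kb, and lay below random lists in 2 of 8 alternatives. Choroid plexus and ependymal genes had 2.89 kb over 8 genes (permutation, 0.993), with Otx2 at 7.28 kb, Msx1 at 5.80 kb and the ciliogenesis gene Foxj1 at 4.71 kb. The direction of the choroid list turned to narrower on the pooled list (1.84 kb, adjusted permutation p = 0.0334) and without replicate 1 (1.61 kb, 0.0179), and Otx2 had 5.67 ± 2.59 kb in the replicates' own lists.

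The 5 lists with fewer than 5 marked genes were not tested for breadth. Without replicate 1 the receptor list had enough marked genes and was narrower (0.513 kb against 2.63 kb, adjusted permutation p = 0.000567). Some genes of these lists had peaks within 5 kb and none within 500 bp of a TSS. Among them were Cd68 (4.04 kb), Apoa2 (2.52 kb), Apoa1 (1.56 kb), Acta1 (2.39 kb), Tnni3 (2.38 kb), Myl7 (1.71 kb), Tnp2 (3.15 kb) and Olfr1344 (1.72 kb). Marked members of these lists included Runx1 (3.36 kb), Irf8 (2.31 kb), Foxa3 (2.18 kb), Zpbp (1.67 kb), Myod1 (1.465 kb), Dazl (1.21 kb), Vmn1r4 (3.03 kb) and Olfr94 (1.72 kb). Fewest bases were found at Ckm, Acr, Ddx4, Olfr1 and Olfr10, which had no replicated peak within 5 kb, and at Actc1, where replicate 2 alone had 0.199 kb.

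**Figure D2:**
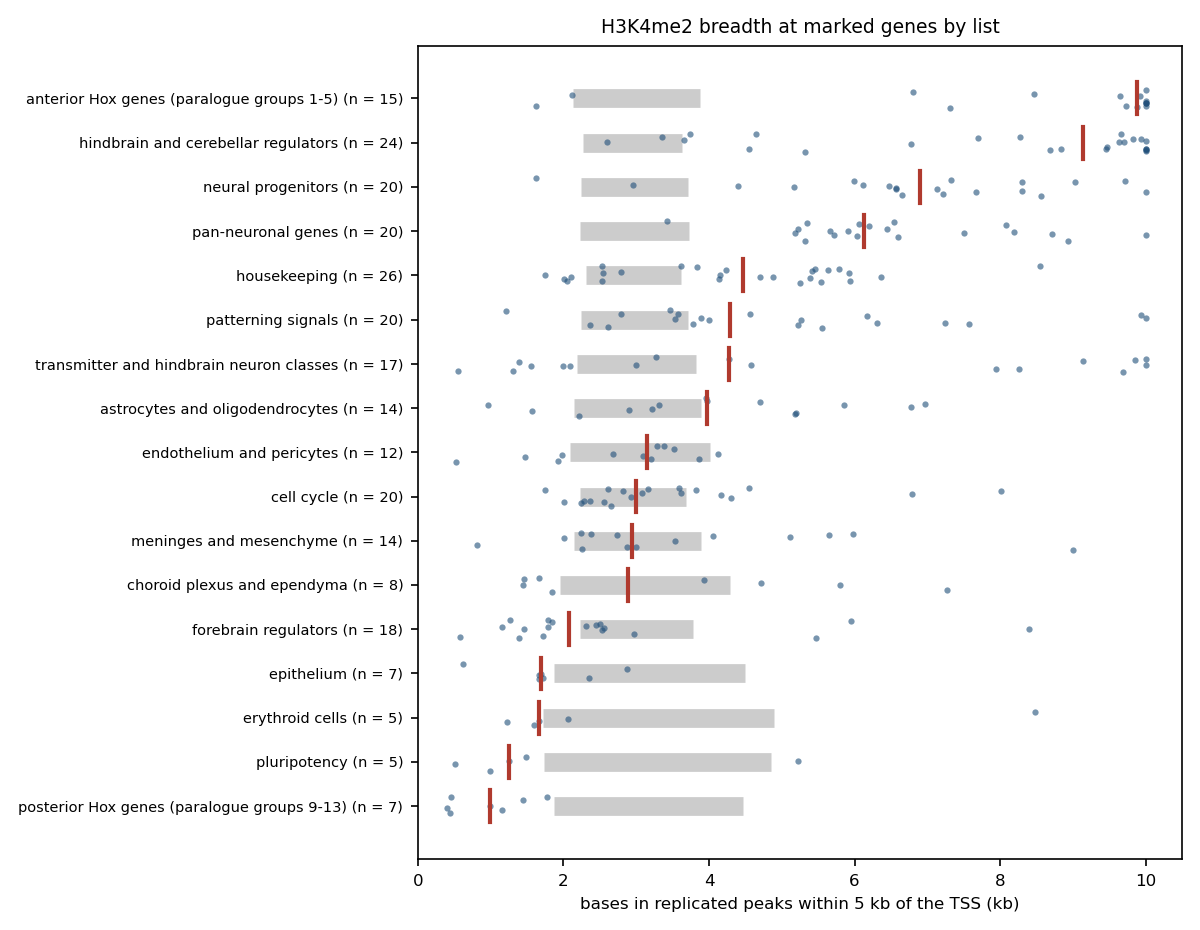
Bases in replicated H3K4me2 peaks within 5 kb of the TSS (horizontal axis, kb, with a ceiling of 10) for each marked gene, by list, where points are genes, red lines are list medians and grey bars hold 95% of the medians of 10000 random lists of marked genes. The medians of hindbrain regulators (9.14 kb) and anterior Hox genes (9.89 kb) lie right of their grey bars, and that of posterior Hox genes (0.989 kb) lies left of its bar.

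Hox genes, which specify position along the head-to-tail axis, were divided by paralogue group. Over the interval from 2 kb upstream of each gene to its end, replicated peaks covered 79.8% ± 27.1 (mean ± SD over 15 genes) of the genes of groups 1 to 5 and 7.25% ± 9.31 (16 genes) of those of groups 9 to 13. The difference of 72.5 percentage points had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. Within 1 kb of the TSS the means were 92.15% and 16.6%. Hoxa2, Hoxa4, Hoxa5, Hoxb2, Hoxb4 and Hoxb5 were covered to 100%, Hoxb3 to 99.2%, Hoxa3 to 95.9%, Hoxc4 to 85.5% and Hoxa1 to 80.5%. Lower shares were found at Hoxd3 (74.5%), Hoxd4 (55.8%), Hoxd1 (50.9%), Hoxb1 (36.1%) and Hoxc5 (17.9%). These shares depend on the annotated span of a gene, which for Hoxc5 (15:102967443-103017429) takes in Hoxc6, Hoxc8 and Hoxc9. Within 5 kb of the TSS, peaks covered 8.46 kb at Hoxc5, 9.92 kb at Hoxd3 and 9.89 kb at Hoxd4. Hoxd1 and Hoxb1 had 2.12 and 1.62 kb there. Group means were 67.3% in group 6, 65.3% in group 7, 41.7% in group 8 and 15.1% in group 9. In group 8, Hoxb8 reached 97.01% (76.8% ± 20.8 in the replicates' own lists, n = 2) and Hoxc8 had no peak. Groups 10, 11 and 12 averaged 2.10%, 1.39% and 2.00%, and group 13 averaged 10.3%, with 19.1% at Hoxa13 and 17.5% at Hoxd13. Neighbouring Hox genes share peaks and are not independent, which the permutation does not take into account.

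A single domain of replicated peaks joined over gaps of up to 1 kb ran across Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6 (11:96294168-96356568, 62.4 kb). Another crossed Hoxa1 to Hoxa6 (6:52156512-52213435, 56.9 kb). Both were the longest of 29779 domains, whose median length was 1.44 kb. After them, among domains with a protein-coding TSS, came those of Zic1 and Zic4, zinc finger genes of the dorsal hindbrain and cerebellum (9:91348899-91389139, 40.2 kb), Meis2 (a Hox cofactor, 34.9 kb), Pou3f3 (31.8 kb), Nr2f2 (30.1 kb), Zfhx3 (28.8 kb), Ebf3 (28.6 kb), Bcl11a with A830031A19Rik (28.1 kb) and Nfib (25.7 kb). In total, 213 domains exceeded 10 kb and 29 exceeded 20 kb.

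**Figure D3:**
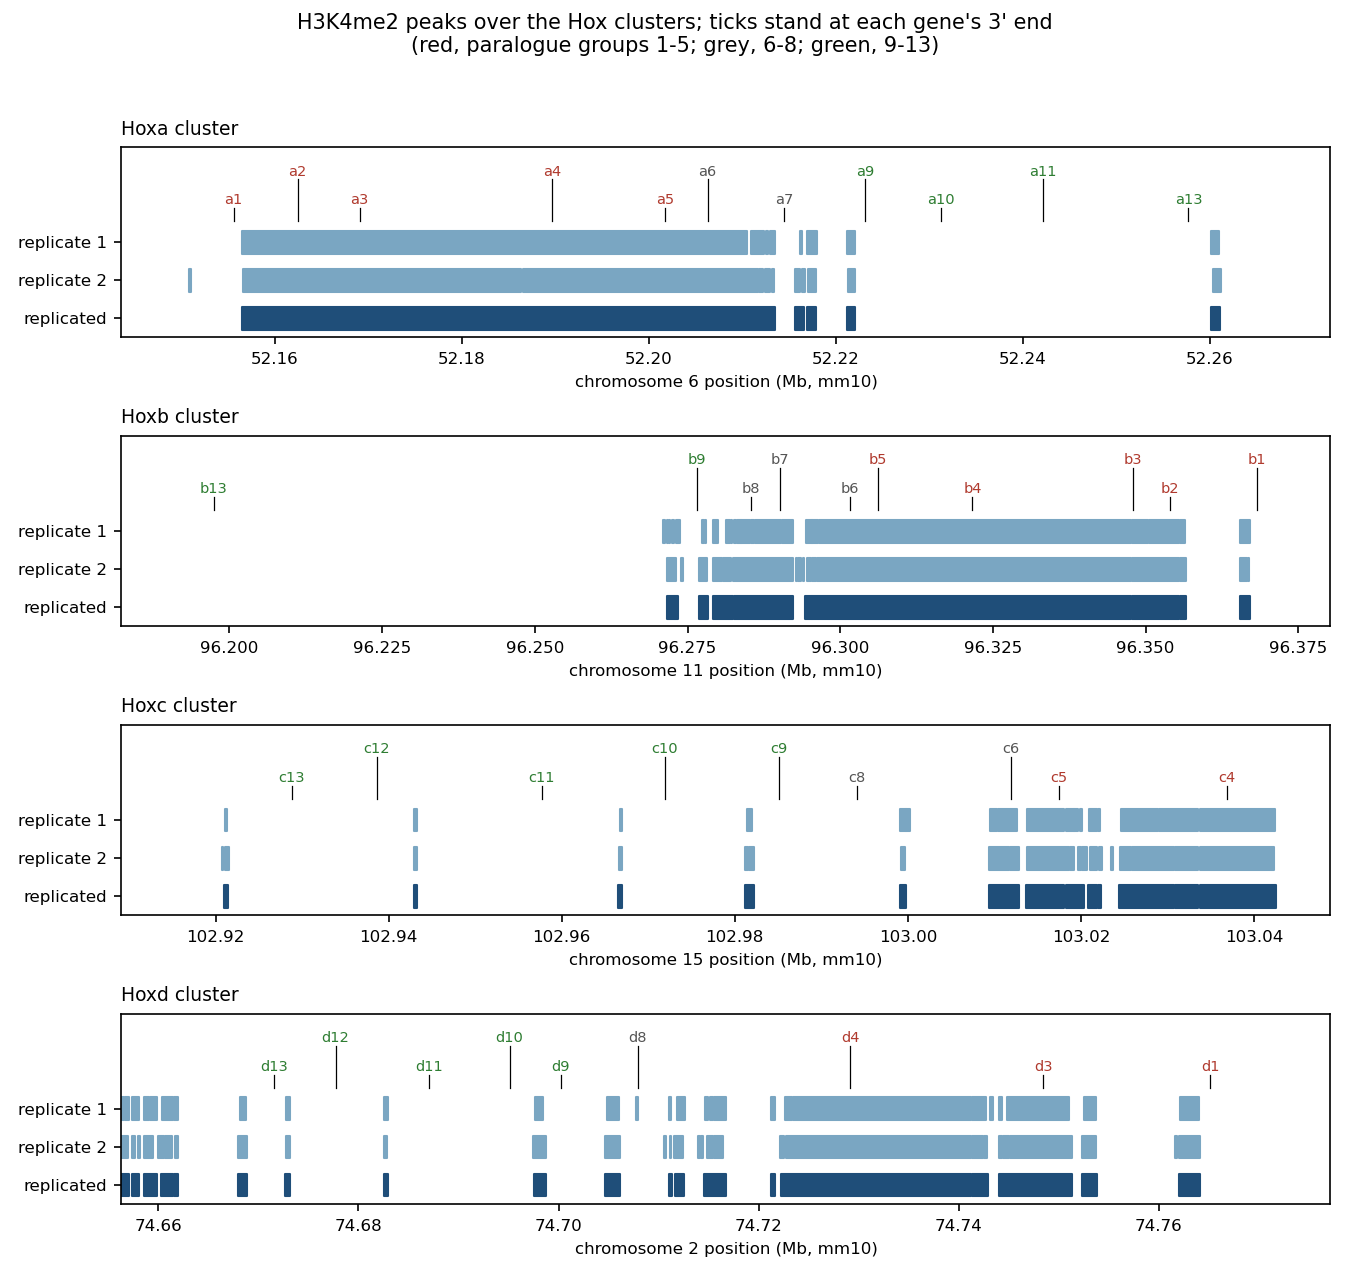
H3K4me2 peaks of replicate 1, replicate 2 and the replicated list over the Hox clusters, drawn to scale on mm10 (horizontal axis, chromosome position in Mb), with ticks at the 3′ end of each gene. Peaks join into domains of 62.4 kb at Hoxb2 to Hoxb6 and 56.9 kb at Hoxa1 to Hoxa6, and groups 10 to 12 hold few peaks (means of 1.39% to 2.10% of each gene covered).

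Distal peaks, more than 2 kb from any TSS, were compared with their flanks for short sequence words. The E-box CAGCTG, bound by proneural factors, stood in 15.6% of 16307 summit windows of 200 bp and in 9.16% of 28582 flanking windows (1.70 times, adjusted p = 3.77e-89 by Fisher's exact test). Also above the flanks were the MEIS word TGACAG (15.97% against 13.5%, 1.18 times, 5.74e-12), GTTGCCA of RFX factors (2.53% against 2.00%, 1.26 times, 0.000995), TTGGCA of NFI factors (10.8% against 9.96%, 0.0144), ACAAAG of SOX factors (18.2% against 17.3%, 0.0189) and TAATTA of homeodomain factors (6.23% against 5.68%, 0.0285). Words below the flanks were the MEF2 word TATTTATA (0.687% against 1.81%, 1.46e-23), the GATA word AGATAA (8.52% against 11%, 1.51e-16), the AP-1 word TGAGTCA, which is the reverse complement of TGACTCA and gives the same count (2.83% against 3.38%, 0.00344), and GTTACCA (1.41% against 1.75%, 0.0125). CAGATG, TGATTGAT, TGATTTAT, CTATAAATAG, CCACTAG and CAAAGTCCA did not differ.

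The word tests were two-sided Fisher's exact tests adjusted over 17 words, with windows as units and not replicates. With flanks matched on GC content, 13078 windows on each side, CAGCTG kept a smaller excess (14.4% against 11.8%, 1.23 times, adjusted p = 9.36e-10 by Fisher's exact test) and TAATTA stood at 2.05 times. The HOX-PBX words then passed as enriched, TGATTTAT at 2.37 times and TGATTGAT at 1.55 times, AGATAA turned to enriched (1.18 times), and the calls of TATTTATA (0.872 times, 0.425), GTTACCA (0.976 times, 0.955) and TTGGCA ended. TTGGCA stood at 1.07 times (0.0852), close to its 1.08 times with all windows. Without replicate 1, TAATTA stood at 0.994 times its flanks (0.916). CAGATG passed as enriched on the pooled list (1.05 times, adjusted p = 0.0155 by Fisher's exact test) and without replicate 2 (1.07 times, 0.00151), and lay at 0.984 times its GC-matched flanks. The call of GTTACCA also ended on the pooled list (0.905 times, 0.148) and without replicate 2 (0.944 times, 0.554). Among words with no call, CTATAAATAG and CCACTAG turned in 1 of 5 alternatives each and CAAAGTCCA in 4 of 5. CTATAAATAG stood at 0.376 times in the replicated list, 0.943 times without replicate 1, 1.005 times without replicate 2 and 1 time with GC-matched flanks.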

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

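Of the tests in this part, those on Hox paralogue group 13 and on replicated peaks missing from a replicate's list were chosen after the result was seen. The reading of the test on endothelial chromatin was changed after its value was seen. Matching breadth on promoter CpG content was written down for broader lists before the data were examined. Its use here, to weigh a cause of the narrowness, was chosen after its result was seen.

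Signal in data that the main comparisons did not use came from 3 sources. The first of them, the pooled list, was used in the alternatives only. The pooled list held 12248 peaks outside the replicated list, with a median width of 259 bp and a median −log10 p of 4.67, and 3664 of them touched no peak of either replicate. There were 15 replicated peaks on unplaced or unlocalised scaffolds. Of the 29 domains longer than 20 kb, 4 held no protein-coding TSS, and all 4 held a gene of the brain microRNAs miR-9 or miR-124.

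Endothelial and pericyte genes differed by the most genes between the replicates among the lists, with 15 of 16 marked in replicate 1 and 12 in replicate 2. The 3 promoters that parted within 500 bp of a TSS, Cdh5, Tek and Tie1, had a median −log10 p of 3.48 in replicate 1. Weak peaks near the calling threshold may account for the difference. The 103 genes with a peak in replicate 1 only also had a low median (4.81). A low value thus follows largely from how the promoters were picked and is no support particular to this list. More endothelial chromatin in replicate 1 was tested on the 12 genes marked in both. Their median log2 ratio of replicate 1 to replicate 2 signal was -0.18, with 5 of 12 above 0, inside the 95% range of random lists (-0.27 to 0.28). The rule written beforehand counted a median at or below that of random lists (-0.000559) against this explanation, and the value met that rule. A demand that it also lie below the range was added after the value was seen. Under that demand the explanation stays open. The embryo pool and the control alignment differ along with the replicate and cannot be told apart. Cell content was weighed here as a technical source. The design has 1 group, so it gives no biological explanation to set against it, and no biological explanation was tested.

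The mark was narrow at the 4 lists of forebrain regulators, posterior Hox genes, epithelium and pluripotency. Their 37 marked members had a promoter CpG observed over expected of 0.726 ± 0.165 against 0.547 ± 0.202 at 22 unmarked members. The difference of 0.180 (two-sided permutation p = 0.00044) goes with CpG content bearing on which members carry a peak. The permutation pooled the 4 lists, so differences between lists enter it, and no list was tested alone. The gap was wide for epithelium (0.705 against 0.380) and pluripotency (0.682 against 0.398) and smaller for posterior Hox genes (0.815 against 0.684) and forebrain regulators (0.712 against 0.658). Posterior Hox genes were also marked at 43.75%, against 94.6% of genes with the same CpG content, so for them it leaves the missing peaks open. The CpG ratio within 500 bp of the TSS as the whole cause of the narrowness is argued against. All 4 lists stayed narrower than marked genes matched on that ratio (adjusted permutation p from 0.000567 to 0.0298). The length of CpG-rich sequence around the TSS was not matched, so its part in the narrowness was not tested. Cells of more caudal neural tube might add peaks at posterior Hox genes, with coverage falling as the group number rises; group 13 instead exceeded groups 10 and 11 by 8.57 points (10.3% against 1.75%, exact permutation p = 0.0857, 4 against 6 genes), which missed the threshold of 0.05 and leaves this open. Those cells were weighed as a matter of tissue content, a technical source. A poised state with a repressive mark was not tested, and no biological explanation was tested.

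Replicated peaks did not always touch a peak in both replicates: 2302 of 35769 (6.44%) lacked one in at least 1 replicate's list. These peaks had a median −log10 p of 7.002 against 97.1 for the others, and only 2 exceeded 20, so weak peaks are a candidate source. The smallest −log10 p of the replicated list was 2.01, so their median lies above the calling threshold. Picking peaks that are missing from a replicate's list itself favours weak peaks, so a low median was likely beforehand. The rule behind the replicated list stays unknown, and no biological explanation was tested.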

How the results depend on the processing

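The alternatives below were planned, except the use of only the most upstream TSS, which was chosen after seeing the data. For breadth they were written for broader lists, and the narrower lists came from the same two-sided tests. Of the main values and counts, 54 alternatives left the direction and the side of the threshold as they were, or the count within 1.5 times, and 7 moved one. The Hox difference ranged from 71.7 to 75.5 points over its 5 alternatives, and the 1 kb window raised the posterior mean to 16.6%. With a −log10 p of at least 5, the shared bases rose to 81.2% and the rank correlation of signal to 0.837, and a reciprocal overlap of 50% gave 0.900. That overlap rule lowered the shared peaks to 65.4% of replicate 1 and 62.4% of replicate 2. Matching on promoter CpG content gave 0 lists with more and 3 lists with fewer marked promoters. Germline and receptor genes kept their call, and posterior Hox genes gained one. Lists marked at every member could not pass as more often marked in that test. The most upstream TSS left 2 narrower lists. The pluripotency list had too few marked genes to test there and without replicate 1. GC-matched flanks left 2 depleted words, TGAGTCA and TGACTCA, which are reverse complements and so a single sequence.

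A direction was reversed in 33 alternatives, 7 of them past the threshold on one side or the other and 26 on neither. The 7 come first. With CpG matching, the erythroid list (33.3% marked) lay above its matched genes. A 2 kb window put transmitter genes at 2.10 kb. Choroid plexus genes fell to 1.84 kb on the pooled list, and ranged from 1.61 to 1.86 kb with either replicate left out. The ratio of TAATTA ranged from 0.994 to 1.11 with either replicate left out. GC-matched flanks put TGATTGAT at 1.55 and AGATAA at 1.18 times.

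The 26 without a call were these, besides the choroid value without replicate 2 in the range above. With CpG matching, 85.7% of forebrain regulators stood below their matched genes, and 60% of astrocyte genes were marked with the most upstream TSS. Choroid plexus genes were marked at 66.7% with a 2 kb window and 58.3% with the most upstream TSS. Epithelial genes were marked at 75% on the pooled list and with a 2 kb window, and at 66.7% with either replicate left out. Breadth turned for cell cycle genes by domain length (2.73 kb). Endothelial genes had 2.93 kb on the pooled list, 1.98 kb with the 2 kb window, 2.31 kb by domain length, 2.68 kb with the most upstream TSS and 2.32 to 2.62 kb with either replicate left out. Meningeal genes had 2.42 kb with the 2 kb window and 2.17 to 3.26 kb with either replicate left out, and choroid plexus genes 2.46 kb with that window. With GC-matched flanks CAGATG stood at 0.984 times and CAAAGTCCA at 0.938 times, and CAAAGTCCA at 0.915 times on the pooled list. With either replicate left out, ratios ranged from 0.9337 to 0.9339 for CAAAGTCCA, 0.943 to 1.005 for CTATAAATAG and 0.973 to 1.034 for CCACTAG.

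The cause was not tested for these or for the moved values, beyond what each setting's construction shows. Among values for single lists, genes and words, 749 alternatives left the result as it was, 218 moved a value with no test, 22 ended a call, 15 made one and 33 reversed a direction. No paired analysis was possible because there is only 1 group. The unknown depth limits how weak peaks can be read.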

Other observations

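All values and gene families in this part were chosen after the data were seen, and the test on distal peaks alone was written before its result was seen. MicroRNA genes of the brain lay in some of the longest domains. Mir9-2 sat in a domain of 33.4 kb (13:83712938-83746301), Mir9-1 in one of 27.9 kb (3:88198181-88226105) and Mir9-3 in one of 24.3 kb (7:79495868-79520193). The genes of miR-124, the most abundant microRNA of neurons, followed with 21.8 kb at Mir124a-2, 15.5 kb at Mir124a-1 and 9.12 kb at Mir124a-3. Of 2202 annotated microRNA genes, 288 lay in any domain and 10 in a domain longer than 15 kb, and those 10 also included Mir10a and Mir10b of the Hox clusters.

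Families of developmental factors were counted, and no test was made between them. All 5 Zic genes, 4 Pou3 genes, 6 Irx genes and 8 Lhx genes were marked, with median breadths of 9.45, 9.65, 8.54 and 6.61 kb. Sox genes were marked at 18 of 19 members, without Sox15. Lower were Fox genes at 36 of 44, Nkx genes at 11 of 14 and Tbx genes at 9 of 13, with medians of 3.06, 3.14 and 2.38 kb. Other families were counted too. Wnt genes were marked at 18 of 19, without Wnt8b. Ribosomal protein genes were marked at 76 of 79, without Rpl10l, Rpl39l and Rpl3l. Clustered protocadherin genes, of which single neurons express a random choice, were marked at 20 of 57 with a median of 1.04 kb, and keratin genes at 5 of 49.

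On the sex chromosomes a smaller share of genes was marked, with lower promoter signal, a difference that was described and not tested. The pools were of mixed sex. Copy number of X and Y in such pools and the mapping of reads to these chromosomes were not examined. On the X chromosome 478 of 948 protein-coding genes were marked (50.4%), against 13871 of 20720 on autosomes (66.9%). The median promoter signal of marked X genes was 0.648 times that of autosomal genes in replicate 1 and 0.660 times in replicate 2. Distal peaks numbered 34.2 per 100 genes on X and 77.1 on autosomes. The marked genes of the Y chromosome were 4 of 183, namely Ddx3y, Eif2s3y, Kdm5d and Uty.

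A hypothesis held that hindbrain and cerebellar regulators have more distal peaks than other marked genes with as much surrounding sequence. Their median was 7.5 distal peaks per gene (mean 7.04 ± 4.54, 24 genes), against a median of 1 in random lists matched on the length of the surrounding sequence, whose 95% range was 0.5 to 2.5 (two-sided permutation p = 0.0002, the smallest these permutations can give; 0.0017 after adjustment over 17 lists). Neural progenitor genes had a median of 4 (adjusted permutation p = 0.0017) and pan-neuronal genes 3 (0.0329). Forebrain regulators had 2.5 (0.0524), astrocyte and oligodendrocyte genes 2 (0.0524) and transmitter genes 2 (0.113). Those last lists missed the threshold, yet their medians lay above the 95% ranges of random lists, whose upper ends were 2, 1.5 and 1. Housekeeping genes had a median of 0. The values go with the hypothesis, though the excess was not particular to this list. Peaks were given to the nearest gene by position alone, and the surrounding sequence was matched in 10 bins of length. Separate peaks of a broad domain at a TSS could count as distal where they lay more than 2 kb away, which was not examined. The genes with the most distal peaks were Zfhx3 with 38, Adgrl2 with 34 and Zfp608 with 26.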
